A study of Mus musculus with 2 samples.

How the data were processed

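RNA was measured in mouse mandibular prominences, the paired facial swellings that form the lower jaw and carry the early tongue. The series holds 2 libraries, 1 per group. Per the labels, each library was made from total RNA of 10 pooled embryos on a mixed CD1 background, prepared with standard Illumina chemistry. One group is called control. In the other, the gene for the kinesin-2 motor subunit Kif3a was floxed and deleted by Wnt1-Cre, which acts in neural crest cells and their descendants. The labels place both groups at embryonic day 11.5. The submitters' naming of the deposited tables gives day 11.5 for the control and day 11 for the mutant, and a different sequencing run for each, so run, and any difference in stage, cannot be told apart from genotype in these libraries.

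The authors deposited 1 table per library with 59120 transcripts under UCSC known gene identifiers. Per the file headers, each line gives a locus, a length, a coverage signal, an FPKM value (fragments scaled to transcript length and to the number of mapped fragments) and a status of the estimate. The naming of the deposited tables gives Cufflinks as the tool that estimated FPKM. Its version, the aligner, any trimming and the strandedness of the libraries are not given in the sources used here. The submitters' processing notes name the genome build mm9. The coordinates were tested against the GENCODE annotation of GRCm38: of 45474 transcripts whose gene symbol occurs in both, 72.1% had a start or an end identical to that of a transcript of the same gene. Coordinates are therefore given as the deposited tables have them, 1-based, on GRCm38.

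In 65 lines of each table a gene name with spaces displaced the columns, so that the FPKM was lost, and these lines were left out. Of the other 59055 transcripts, 404 in the control carried the status LOWDATA and 6 in the mutant the status FAIL, and all others were marked OK. FPKM was summed over the transcripts of a gene symbol, which gave 30723 genes. The 12259 genes with a mean FPKM of 1 or more over both libraries were compared. The log2 ratio of a gene is log2((mutant FPKM + 1) / (control FPKM + 1)) on the values as deposited, with a pseudocount of 1, and this understates the difference of genes with low values. A gene was counted as 2-fold higher or lower at a log2 ratio of at least 1 or at most -1.

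With 1 library per group no test between conditions exists, and no difference here has a replicate check. No p-value was computed. The deposited coverage was used to approximate depth. Coverage times length summed to 3850000000 bases in the control and 3760000000 in the mutant, rounded. Among genes with 1 transcript of over 1500 bases, the lowest values clustered near 157 bases in the control and 156 in the mutant, the median of values between 80 and 220 bases, which was taken as the yield of 1 fragment. The steps were blurred, so fragment numbers are approximate: about 24500000 in the control and 24000000 in the mutant, rounded. A ratio of FPKM carries a 95% interval, the exact Clopper-Pearson binomial interval on these approximate fragments. It covers counting error only, not the variation between embryos, dissections or library preparations.

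The gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Of 36 lists, 32 had at least 3 members over the filter. The 30 of these that are not the large patterning factor and secreted signal families were described by the median log2 ratio of these members and its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. Such a percentile describes these libraries and is not a test of the genotype. Genes of the same list can vary together, which random lists do not reproduce. Extreme percentiles were common here: the endothelial, connective tissue and ribosomal protein lists also lay at 0, and oral epithelium at 100. The list of mitochondrial genes was taken by chromosome after its name pattern matched no gene. Named genes were Kif3a; up to 4 members of each list with the largest absolute log2 ratio, and its most abundant member; every Hedgehog target; the 10 highest and 10 lowest of 7999 genes with a mean FPKM of 5 or more; and the 6 highest and 6 lowest members of the patterning factor and secreted signal families. The ranking left out 874 genes: 731 with predicted or clone names, 81 ribosomal protein, 41 small RNA, 8 mitochondrial, 6 globin, 4 histone and 2 Y-linked genes, and Xist. The clone names include accession-type symbols other than those written down at first, and the globin gene Beta-s was added to the globins after it had ranked lowest. Beta-s, Hbb-b1, the clone AK204943, Hoxa2 and Hoxb2 are named after their values were seen. A few genes that the rule selects are not reported here.

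The alternatives were pseudocounts of 0.1 and 5, no filter, a mean FPKM of 5 or more, centring on the median gene, scaling to the 75th percentile, TPM-like scaling to a common total after removal of globin, mitochondrial, small RNA, ribosomal protein and histone genes, the most abundant transcript alone, transcripts marked OK in both libraries, random lists without matching, and 5 expression bins. Added after seeing the data were the removal of a lowess trend (fraction 0.3) of log2 ratio on transcript length, TPM-like scaling that also leaves out transcripts under 200 bases, and random lists matched on expression and length in 5 by 5 bins. The length of a gene is that of its transcript with the highest mean FPKM. The procedure was tested on simulated libraries with counting noise alone over the 12259 genes: 100% of 100 genes made 4-fold higher and 93.8% of 97 genes made 4-fold lower passed the 2-fold rule, as did 0.00834% of unchanged genes. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.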

Results

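Gene expression in the mandibular prominence was compared between 1 control library and 1 library of embryos in which the ciliary motor gene Kif3a was deleted in the neural crest, each from 10 pooled embryos. The title of the series concerns the processing of GLI proteins, the transcription factors of the Hedgehog pathway, which takes place at the primary cilium, and the development of the tongue. The comparison addresses which genes differ in the jaw primordium when neural crest cells lack this motor. The libraries held about 24500000 fragments in the control and 24000000 in the mutant. Values are FPKM of 1 library each, without replicates, and intervals in parentheses are 95% counting intervals.

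Kif3a, on chromosome 11 from 53567379 to 53604244, stood at 11.46 FPKM in the control and 5.39 in the mutant. The mutant value was 0.471 of the control value (0.431 to 0.514), a log2 ratio of -0.96. Its most abundant transcript, of 5438 bases, stood at 9.57 and 4.18 FPKM. Of the others, the one of 5429 bases went the other way, at 0.159 and 1.14 FPKM, while those of 5417 and 526 bases stood at 0.761 and 0.970 in the control and at 0.000129 and 0.0743 in the mutant. The tissue also holds epithelium, muscle precursors, endothelium and blood, which do not derive from Wnt1-Cre cells, and the value covers the whole transcript rather than the deleted part.

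Of the 12259 genes compared, 94 were at least 2-fold higher in the mutant and 167 at least 2-fold lower. The genes with established names made up 27 of the higher and 105 of the lower ones. Small RNA genes gave 22 and 6, and predicted or clone names 43 and 48. The median log2 ratio of all genes was -0.13, and 97.9% of genes lay within 2-fold. The balance of higher and lower genes depended on the scaling. It was 132 to 129 after centring on the median gene, 125 to 137 with upper quartile scaling, 827 to 83 with TPM-like scaling, 214 to 178 when transcripts under 200 bases were also left out of that scaling, and 126 to 109 after removal of the length trend. TPM-like scaling moved the median of all genes to 0.48, because the 75-base clone AK204943 alone held 24.5% of all FPKM in the control and 4.24% in the mutant. On that scale small negative log2 ratios turned positive, so directions of gene groups are given relative to the median gene.

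Among the 7999 ranked genes, all with a mean FPKM of 5 or more, the 10 with the lowest log2 ratios included 4 forkhead factors. Outside this ranking, small RNA genes ranged from -4.40 to 9.60. Beta-s (-3.48) and the clone AK204943 (-3.12) were lower than all 10, and Hba-a2 (-2.37) and Myog (-2.19) were lower than some. The forkhead gene Foxf1 had -2.43 and was 6.56-fold lower in the mutant (5.30 to 8.19), at 24.5 and 3.74 FPKM. Zcchc5, a gene of retrotransposon origin, had -2.32 and was 7.86-fold lower (6.42 to 9.70) at 10.99 and 1.40 FPKM, and Foxf2 had -2.30 and was 6.27-fold lower (5.36 to 7.35). The steroid dehydrogenase gene Hsd3b6 (-2.09), Foxd1 (-2.05), the cardiac alpha actin gene Actc1 (-2.02), which embryonic skeletal muscle also expresses, Foxd2 (-1.86), the membrane protein gene Pdzk1ip1 (-1.82), the opioid precursor gene Penk (-1.77) and the matrix protein gene Postn (-1.65) came next. The 10 highest of the ranked genes were led by the nuclear noncoding RNA Malat1. It stood at 10.98 FPKM in the control and 63.7 in the mutant, a ratio of 5.81 (5.53 to 6.10). The osmotic stress factor Nfat5 (1.42), the kinase Hipk2 (1.37), Zbed6 (1.24), the ubiquitin ligase Cbl (1.22), the pseudogene Tmem181b-ps (1.17), the histone methyltransferase Mll2 (1.17), Ubn2 (1.15), the chromatin remodeller Srcap (1.13) and the apoptosis inhibitor Birc6 (1.06) followed. Long transcripts were higher in the mutant library in general, as described further on, and Birc6, Mll2 and Ubn2, with transcripts of 16212, 19827 and 14669 bases, had log2 ratios of 0.46, 0.46 and 0.61 once the length trend was removed. With the most abundant transcript alone, Nfat5 (0.78), Tmem181b-ps (0.91), Ubn2 (0.57) and Birc6 (0.93) were less than 2-fold higher.

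The Hedgehog target genes were lower in the mutant. All 10 members over the filter had a log2 ratio below 0 and 9 lay below the median gene, 6 of them were at least 2-fold lower, and their median was -1.63, lower than that of all 10000 random lists. The 6 were forkhead genes. Foxf1, Foxc2 and Foxl1 lie together on chromosome 8, at 121084474, 121116171 and 121127685. Foxc2 was 3.40-fold lower (2.94 to 3.96), and Foxl1, at 2.96 and 0.180 FPKM, was 16.4-fold lower (9.41 to 31.4) on about 208 and 13 fragments. Foxf2 lies beside Foxc1 on chromosome 13, at 31625816 and 31806646, and Foxc1 had a log2 ratio of -0.61. Gli1, on chromosome 10 from 127329882 to 127341886 and a direct readout of the pathway, stood at 16.7 and 8.14 FPKM, 2.06-fold lower (1.88 to 2.26).

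Not all targets differed this much. The receptor gene Ptch1, the most abundant target, stood at 47.7 and 38.3 FPKM, a log2 ratio of -0.31, and lay below the median gene under every alternative. Hhip, a decoy receptor for Hedgehog ligands, was below the filter at 0.558 and 1.02 FPKM. It went the other way, 1.82-fold higher in the mutant (1.47 to 2.27) on about 129 and 257 fragments. The transcript of Hhip has 9078 bases, and genes of 8000 to 12000 bases had a median log2 ratio of 0.27. Part of its difference may therefore follow transcript length, and no length-corrected value exists for a gene under the filter. The median of the list stayed between -1.99 and -0.84 under all alternatives, and it was -1.49 with the length trend removed.

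**Figure D1:**
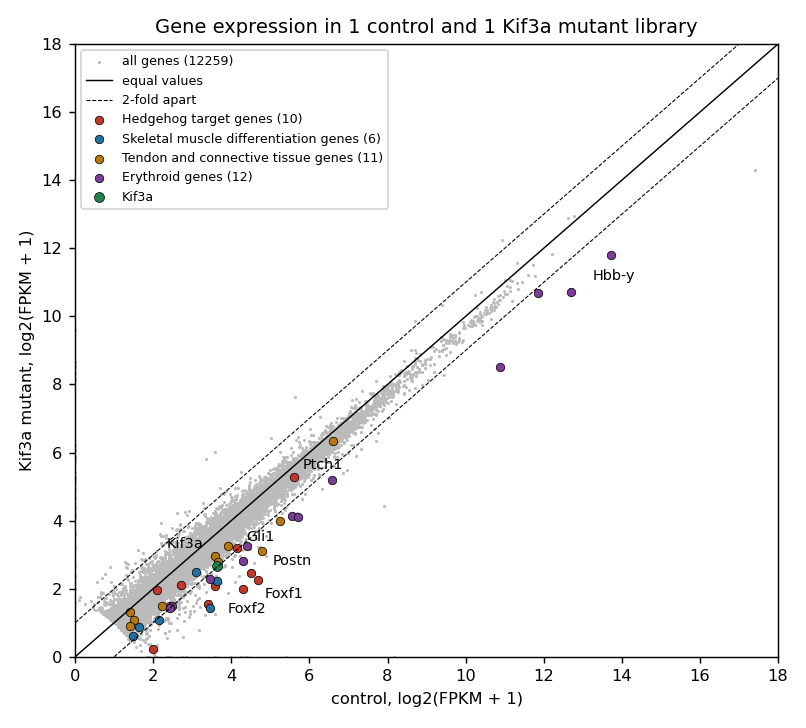
Log2(FPKM + 1) of each of 12259 genes in the control library (horizontal axis) against the Kif3a mutant library (vertical axis), with 4 gene lists and Kif3a in colour, a solid line at equal values and dashed lines at 2-fold. Foxf1 (24.5 and 3.74 FPKM) and Foxf2 lie below the lower dashed line, while Ptch1 (47.7 and 38.3 FPKM) lies near the solid line.

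The ligands and transducers of the pathway did not share this difference. Their 16 measured members had a median log2 ratio of -0.05, at percentile 81.4 of the random lists. Shh, the epithelial ligand, was the exception: it stood at 4.06 FPKM in the control and 9.39 in the mutant, a ratio of 2.31 (2.004 to 2.67). Gpr161 had a log2 ratio of 0.34, Gli3 of 0.28 and Hhat of -0.37. With the length trend removed, Gpr161 had 0.55, Gli3, with a transcript of 8426 bases, 0.04, and Hhat -0.23. The most abundant member, the coreceptor Gas1, stood at 79.4 and 85.0 FPKM. The 39 kinesin-2, intraflagellar transport and ciliary genes had a median of -0.05, at percentile 76.3. Kif3a itself was the lowest of them, and Dync2li1 (-0.56), Bbs7 (-0.52) and Cep290 (0.42) came next in size. Without the length trend, Dync2li1 had -0.31, Bbs7 -0.36 and Cep290 0.21. Ift20, the most abundant on average, stood at 31.8 and 29.98 FPKM. Relative to the median gene, both medians changed sign once the length trend was removed.

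Genes of skeletal muscle, which forms the bulk of the later tongue, were lower in the mutant. All 6 measured differentiation genes were lower, 3 of them at least 2-fold (2 after centring on the median gene). Their median log2 ratio was -0.97, below all 10000 random lists. Actc1 stood at 9.96 and 1.71 FPKM, the slow troponin gene Tnnt1 at 11.4 and 3.65, the myosin light chain gene Mylpf at 3.44 and 1.095, and the troponin gene Tnni1 at 1.79 and 0.532. The other 18 members lay under the filter. Among 8 progenitor factors the median was -0.57, at percentile 0.07, and the members were unlike each other. The myogenic regulators Myog and Myod1 stood at 5.78 and 3.89 FPKM in the control against 0.488 and 0.636 in the mutant, 11.8-fold (7.39 to 20.04) and 6.13-fold (4.13 to 9.41) lower. Msc (-0.97) and Tbx1 (-0.72), which act in head muscle precursors, were lower as well, while 2 of the 8 had log2 ratios above 0.

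Connective tissue and bone genes were also lower. All 11 measured tendon and connective tissue genes had log2 ratios below 0, 10 lay below the median gene and 2 were at least 2-fold lower. Their median was -0.67, below all 10000 random lists. Postn was 3.42-fold lower (3.14 to 3.74) at 26.3 and 7.69 FPKM, and the transcription factor gene Osr1 2.47-fold lower (2.27 to 2.68) at 36.8 and 14.9. Tnc (-0.94) and Osr2 (-0.90) followed, and the most abundant member, Col3a1, had -0.26 and lay below the median gene under every alternative. Of 11 bone genes, 5 passed the filter, 4 of them below the median gene and 0 at least 2-fold lower. Their median was -0.56, at percentile 0.315, which is the value of Sp7, a gene near the filter at 1.42 and 0.642 FPKM. Type I collagen genes Col1a1 and Col1a2 had log2 ratios of -0.91 and -0.74, and the osteoblast factors Sp7 and Runx2 -0.56 and -0.34, though Runx2 lay above the median gene when its most abundant transcript alone was used. The 9 cartilage genes had a median of 0.15, at percentile 98.2, but at 92.4 among lists also matched on length. Hapln1 (0.57), Col11a1 (0.54) and Sox5 (0.30) were higher and Col9a2 (-0.58) lower, with Col2a1 at 55.6 and 59.3 FPKM. Col11a1 had -0.06 when its most abundant transcript alone was used, still above the median gene.

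Regional patterning genes of the jaw moved in both directions. The 12 distal mandibular mesenchyme factors had a median log2 ratio of 0.16, at percentile 99.97. Gata3 (0.53), Tbx3 (0.49) and Msx2 (0.42) were higher in the mutant. Hand2, the most abundant of them at 89.9 and 67.4 FPKM, had a log2 ratio of -0.41 and lay below the median gene under every alternative. The 24 first arch factors had a median of -0.12, at percentile 78.7. Pou3f3 was 4.08-fold lower (3.34 to 5.01), and Nkx3-2 (-0.94), Dlx4 (-0.75) and Gsc (-0.62) were lower, though Dlx4 lay above the median gene when its most abundant transcript alone was used. Twist1, the most abundant, stood at 181 and 137 FPKM.

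Oral epithelial genes were higher relative to the median gene, with a median of 0.27 over 17 members, above all 10000 random lists. Of the 17, 0 were at least 2-fold higher and 1, Krt15, was at least 2-fold lower. Esrp2 (0.56) and Cldn6, at 31.0 and 39.6 FPKM, were higher. The basal keratin genes Krt15 and Krt5 went the other way, with log2 ratios of -1.13 and -0.72, and Krt19 had -0.54. Signalling pathways other than Hedgehog showed small differences as groups. The 18 WNT genes had a median of -0.22, at percentile 7.80, with Apcdd1 (-0.75) and Nkd1 (-0.52) lower and Znrf3 (0.57) and Dkk1 (0.54) higher. The 12 FGF pathway genes had 0.02, at percentile 93.8, with Fgf8 at 12.9 and 17.4 FPKM, Etv4 at -0.30, Etv5 at -0.21, Etv1 at -0.18 and the most abundant, Dusp6, at 35.4 and 38.6 FPKM. The 14 BMP pathway genes had -0.08, at percentile 72.1, with Bmp2 (-0.67), Bmper (-0.54) and Bmp5 (-0.44) lower and Smad9 (0.59) higher; the most abundant, Id3, stood at 181 and 153 FPKM.

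**Figure D2:**
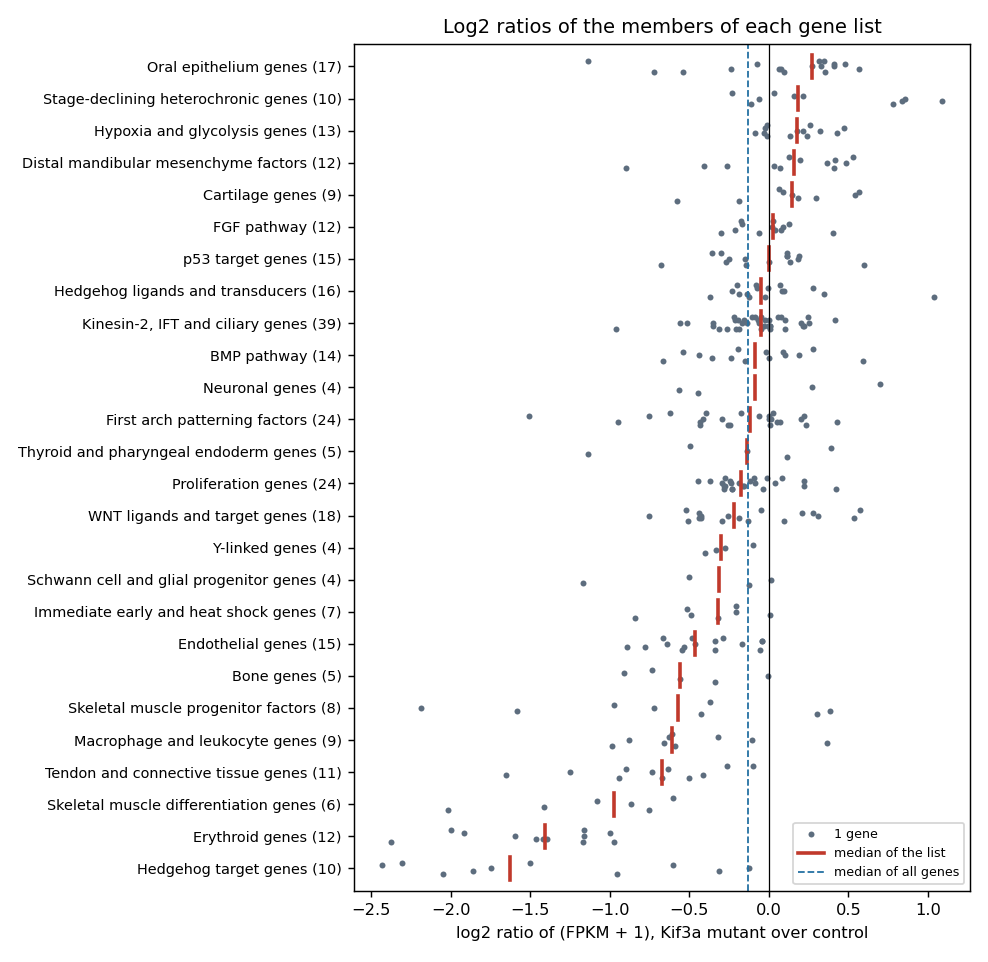
Log2 ratio of (FPKM + 1), Kif3a mutant over control, of each gene over the filter (points) in 26 gene lists, with each list's median (red bars), the median of all genes (dashed blue line) and the number of genes in parentheses. The Hedgehog targets have the lowest median, -1.63, followed by the erythroid genes, -1.40, and the muscle differentiation genes, -0.97.

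Blood and vessel genes were lower in the mutant pool. All 12 erythroid genes had log2 ratios below 0 and 11 were at least 2-fold lower (10 after centring on the median gene, 7 with the length trend removed and 3 with TPM-like scaling, which shifts all genes upward), with a median of -1.40, below all 10000 random lists. The embryonic globin gene Hbb-y, the most abundant, stood at 13483 and 3572 FPKM, Hba-x at 6676 and 1672, and Hba-a2 at 1883 and 362, while the anion exchanger gene Slc4a1 was 3.15-fold lower (2.99 to 3.31). The Hba-a2 value sums 2 transcripts between 32283672 and 32297310 on chromosome 11, of which the most abundant has 566 bases. It therefore appears to pool Hba-a2 and its near-identical neighbour. All 15 endothelial genes had log2 ratios below 0 and 12 lay below the median gene, but 0 were at least 2-fold lower. Their median was -0.47, below all random lists; it was 0.15 with TPM-like scaling but below the median gene under every alternative. Sox18 (-0.89), Cldn5 (-0.78), Robo4 (-0.66) and Esam (-0.64) were lowest, and Plvap, a marker of fenestrated vessels, stood at 16.0 and 11.3 FPKM. Of the 9 measured macrophage and leukocyte genes, 7 lay below the median gene and 0 were at least 2-fold lower. Their median was -0.61, at percentile 0.05, with Lyz2 (-0.98), Fcer1g (-0.88), C1qa (-0.66) and Laptm5 (-0.63) lower and C1qb at 3.82 and 3.47 FPKM.

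Markers of neighbouring tissues were low in both libraries. Of 16 neuronal genes only 4 passed the filter, with a median of -0.08 at percentile 49.3. Isl1 had a log2 ratio of 0.70, Nefl of -0.56 and Tubb3 of -0.44. Dcx had 0.27, or 0.003 once the length trend was removed. The 4 measured Schwann and glial genes had a median of -0.31 at percentile 13.4, with Fabp7 (-1.16) and Ednrb (-0.50) lower and Erbb3 at 3.93 and 3.97 FPKM. Hox genes of the second and more posterior arches did not reach the filter, and the most abundant of them were lower in the mutant. Hoxb2 stood at 1.18 and 0.605 FPKM, 1.95-fold lower (1.19 to 3.29) on about 47 and 26 fragments, and Hoxa2 at 0.867 and 0.187, 4.63-fold lower (2.11 to 11.6) on about 35 and 8. Only Emx1 and Lhx2 of the brain genes and Nkx2-5 and Hopx of the cardiac genes passed it. Emx1 stood at 0.976 and 1.81 FPKM, Lhx2 at 1.15 and 0.932, Nkx2-5 at 2.72 and 1.32, and Hopx at 1.18 and 0.836. Of the 5 thyroid and pharyngeal endoderm genes, with a median of -0.14 at percentile 35.9, Pax1 was lowest at 2.15 and 0.433 FPKM, Foxe1 had -0.49, Foxa2 0.39 and Foxa1 -0.14.

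Genes that mark cell state and stage differed modestly. The 24 proliferation genes had a median of -0.17, at percentile 74.3, with Mki67 at 0.42, or 0.10 once the length trend was removed, Tyms at -0.44, Ccnb2 at -0.37, Aurkb at -0.29 and Pcna, the most abundant, at 381 and 313 FPKM. Among the 15 p53 targets, with a median of 0.00 at percentile 90.8, Cdkn1a (0.60) was higher and Plk2 (-0.68) lower; Bax had -0.36 and Ei24 -0.30. The 7 immediate early and heat shock genes had -0.32, at percentile 6.04, with Jun (-0.84), Ier3 (-0.51), Zfp36 (-0.49) and Nr4a1 (-0.32) lower and Ier2 at 49.7 and 43.0 FPKM. The 13 hypoxia and glycolysis genes had 0.18, at percentile 99.96, with Pdk1 (0.47), Hk2 (0.43), Eno1 (0.32) and Bnip3 (0.26) higher. The 10 genes known to decline with embryonic stage had 0.19, at percentile 99.91. Trim71 was 2.78-fold higher in the mutant (2.39 to 3.25), and Prtg (0.86), Lin28b (0.84) and Lin28a (0.78) were higher too, while Hmga2 stood at 266 and 254 FPKM. Both pools held transcripts of both sexes: Xist stood at 31.6 and 84.2 FPKM, a log2 ratio of 1.38 that was 0.73 for its transcript of 17918 bases once the length trend was removed. The 4 Y-linked genes had a median of -0.30, at percentile 9.69, with Eif2s3y at 9.42 and 7.28 FPKM, Ddx3y at -0.40, Kdm5d at -0.28 and Uty at -0.10.

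The libraries differed in a way that followed transcript length. Across 12259 genes, which are not independent replicates, the Spearman correlation of log2 ratio with transcript length was 0.407. The median log2 ratio was 0.04 for 120 genes of up to 300 bases, which ran against the trend and varied widely (25th to 75th percentile -0.67 to 1.33). It was -0.31 for 1088 genes of 300 to 1000 bases, -0.14 for 4951 genes of 2000 to 4000 bases and 0.62 for 64 genes longer than 12000 bases. Among genes of basic machinery, 81 ribosomal protein genes had a median of -0.38, below all random lists matched on expression, while 9 mitochondrially encoded genes had 0.28, above all of them. With the length trend removed these medians were -0.11 and 0.54. The 17 histone genes had -0.24, at percentile 4.80, and -0.06 without the length trend. The 51 small RNA genes had 0.62, above all random lists, and 0.78 without it. Of the 27 higher and 105 lower genes with established names, 22 and 59 stayed past 2-fold once the length trend was removed.

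**Figure D3:**
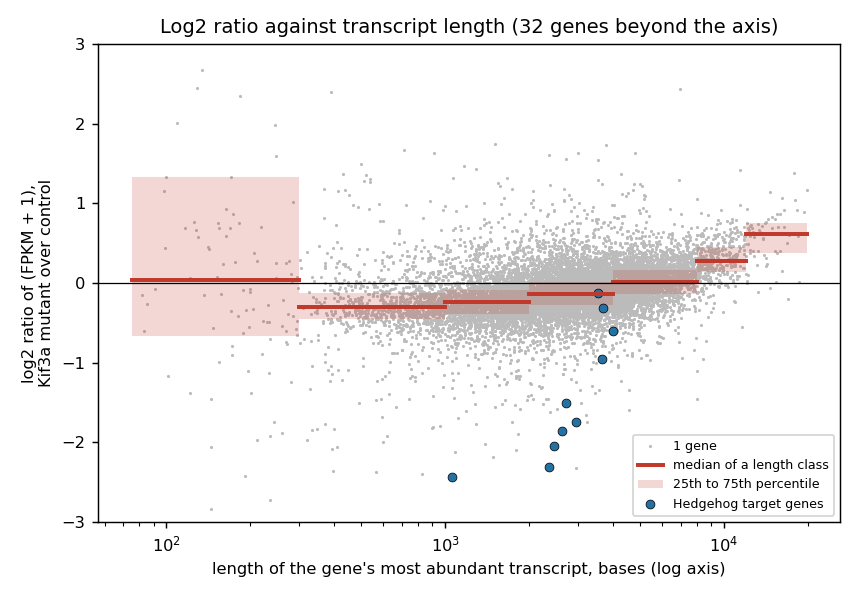
Log2 ratio of (FPKM + 1), Kif3a mutant over control, against the length in bases of each gene's most abundant transcript (log axis), with medians (red lines) and 25th to 75th percentiles (shading) of 7 length classes; 32 genes lie beyond the vertical axis. The class medians go from -0.31 at 300 to 1000 bases to 0.62 above 12000 bases, but the shortest class, up to 300 bases, has 0.04, and most Hedgehog targets (blue) lie below the shading.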

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

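In the 65 lines whose columns were displaced, 1 transcript, named M31 chromobox in the deposited tables, had a coverage of 115 in the mutant against 81.8 in the control and enters no comparison above. It lies on chromosome 11 from 96807201 to 96808147 and is 947 bases long. After allowing for the different coverage per FPKM of the libraries, its mutant value was 1.23 of the control value (1.09 to 1.38, counting error only). Of the other displaced lines with a coverage, MHC B7.2 had a ratio of 1.24 (0.687 to 2.22), on about 22 and 31 fragments in the control and the mutant. EIG 180 was lower in the mutant, with a ratio of 0.468 (0.371 to 0.590) on about 217 and 117 fragments. It lies on chromosome 18 from 62952903 to 62953655 and overlaps Apcdd1 (-0.75), which ends at 62953195, so they may share signal.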

How the results depend on the processing

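The length correction and the TPM-like scaling without transcripts under 200 bases were chosen after seeing the data. Under the 9 planned and 2 added alternatives for ratios, no named gene past 2-fold in the values as deposited changed sign, nor did the Hedgehog and erythroid medians. Little follows from this. Pseudocounts and filters on level cannot turn the sign of a gene. The scalings shifted the median gene too little to turn a log2 ratio past 1 or -1. Of 32 list medians, 16 changed sign with TPM-like scaling, 9 when it left out transcripts under 200 bases and at most 5 under any other. The Hedgehog target median ranged from -1.99 to -0.84. Kif3a stayed lower, at -0.66 with a pseudocount of 5, -0.83 after centring and -0.41 with TPM-like scaling, against -0.96. Against 94 higher and 167 lower genes, a pseudocount of 0.1 gave 179 and 312, a pseudocount of 5 gave 36 and 56, and a mean FPKM of 5 or more, which compares fewer genes, gave 54 and 88. TPM-like scaling gave 827 and 83; all 94 higher genes were among the 827, and the 83 were all among the 167. Without transcripts under 200 bases that scaling gave 214 higher genes, and removal of the length trend gave 109 lower ones. The median log2 ratio of all genes, -0.13, was -0.147 with a pseudocount of 0.1, -0.0895 with a pseudocount of 5, -0.0544 without a filter, -0.145 at a mean FPKM of 5 or more, 0 after centring, -0.0111 with upper quartile scaling, 0.48 with TPM-like scaling, 0.0537 without transcripts under 200 bases, -0.152 with the most abundant transcript and -0.0057 without the length trend. Centring, the scalings and the length correction shift the genes by construction. A larger pseudocount draws every log2 ratio toward 0, also by construction. Filters on level change which genes enter the median, not the ratio of a gene. For the other settings the cause was not tested. Of 44 named genes past 2-fold, 23 stayed so with a pseudocount of 5, 35 with TPM-like scaling and 33 without the length trend. Matching random lists on length moved the cartilage percentile from 98.2 to 92.4 and the Y-linked one from 9.69 to 2.19. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out and no other split exists. Depth limits low genes: Foxl1 and Myog rest on about 13 and 19 fragments in the mutant.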

Other observations

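The patterning factor families, also fixed beforehand, held 211 measured genes, of which 15 were at least 2-fold lower in the mutant and 0 higher. These 15 include the 6 forkhead Hedgehog targets described above, so the 2 counts are not separate observations. The lower ones were 5 with a pseudocount of 5, 7 of 126 at a mean FPKM of 5 or more and 24 with a pseudocount of 0.1, and TPM-like scaling, which shifts all genes upward, gave 22 higher and 11 lower. The lowest were Foxf1, Foxf2, Foxd1, Foxd2, Foxl1 and Pou3f3. The highest were Isl1 (0.70), Tlx1 (0.67), Pou2f1 (0.63), Six4 (0.62), Gbx2 (0.59) and Klf7 (0.58); Pou2f1, with a transcript of 12906 bases, had 0.16 without the length trend. The secreted signal families held 132 measured genes, taken by symbol, and not all of them encode secreted proteins. Among them, Shh was the 1 gene at least 2-fold higher (0.67 with a pseudocount of 5). Nrg1 (0.84), Gdf6 (0.80), the receptor gene Bmpr2 (0.76), Sema3d (0.63) and Dkk1 (0.54) followed. For these 132 genes TPM-like scaling gave 13 higher and 0 lower, or 4 and 1 when transcripts under 200 bases were also left out. The WNT antagonist Sfrp2 (-1.10), the matrix protein gene Tgfbi (-1.01) and Fgf13 (-1.004) were lower. These 3 were past 2-fold in the values as deposited but not after centring on the median gene (-0.97, -0.88 and -0.87) or removal of the length trend (-0.90, -0.86 and -0.84). The WNT agonists Rspo3 (-0.89) and Rspo1 (-0.81) and the growth factor binding protein gene Igfbp3 (-0.84) came next.

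The tests on nuclear RNA, on vessels and on both erythroid explanations below were written after related values had been seen. The first pattern is that long transcripts were higher in the mutant library. With genes at least 2-fold apart left out, the Spearman correlation of log2 ratio with length across 11998 genes was 0.414, so the trend is not carried by the genes that differ most and may reflect a difference between the libraries or runs. A larger share of retained nuclear RNA in the mutant library stays open: 8 nuclear long noncoding RNAs had a median length-corrected log2 ratio of 0.527 (they ranged from -0.24 to 2.30), but 0.243 in the 6 that remain without Malat1 and Xist, whose values had been seen. Run and genotype cannot be told apart here, and no biological explanation was tested.

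The second pattern is the low level of the Hedgehog targets. The length trend accounts for little of it, since the median went from -1.63 to -1.49 when the trend was removed. As the only cause, a smaller share of vessels is argued against by 7 of the 10 measured targets, which lie below the lowest endothelial gene, Sox18. A partial contribution of vessels is not excluded by this. Smaller shares of blood or of second arch tissue were not tested for the targets: the erythroid genes had a median of -1.40, and Hoxa2 was 4.63-fold lower. Whether younger mutant embryos could account for part of it cannot be told apart from genotype, because no younger control was measured; the stage-declining genes lie at percentile 99.5 of lists matched on expression and length, and the submitters' naming gives day 11 for the mutant. Genotype itself also stays open, as untested.

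The third pattern is the low level of erythroid genes. A smaller share of blood in the mutant pool would lower them alike; the median of 5 globin genes was lower than that of 7 other erythroid genes by a log2 difference of -0.746, which falls between the bounds set for and against it, so this stays open. A younger mutant pool is in line with the ratio of Hba-a2 to the earlier Hba-x, whose mutant value was 0.769 of the control value, and the ratio of the early Hbb-bh1 to Hbb-y was 1.68 times the control value. The adult-type Hbb-b1 alone went the other way relative to Hbb-y, at 1.41 times the control value, but at 0.631 when summed with Beta-s, with which it shares fragments. Genotype itself remains an untested explanation.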
